A study of Mus musculus with 24 samples.

How the data were processed

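The study covers 24 libraries, with 2 in each group of WT, Cnot6l-/- and Btg4-/- mice (C57BL/6, postnatal day 21) at GV, MI, MII and zygote. Per the labels, GV oocytes were collected 48 h after PMSG, MI and MII oocytes after 8 and 16 h of culture, and zygotes 24 h after hCG. The labels give the number of oocytes per library differently: the extraction protocol states 100 and the description of the series 2. Libraries were made with Smart-Seq2 and the Tn5 transposase. The authors called bases with CASAVA 1.8, mapped reads to mm9 with TopHat2 2.0.11 and Bowtie2 2.1.0 and estimated expression with Cufflinks 2.2.1. The deposited values are FPKM with 2 decimals for 23235 genes. How the FPKM were scaled between libraries is not given in the sources used here. Summed FPKM fell about 8-fold from GV to zygote in WT, so the values are not shares of a fixed total, although the design written before the data were examined had assumed that they were. Read depth is unknown, and FPKM do not carry the counting error, so precision rests on the spread between libraries.

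The table of all 24 libraries was used. The tables of single libraries were not used, since part of their lines repeat those of another table. The MI columns carry the numbers 2 and 3 while their titles carry 1 and 2, so they were assigned to their groups only. Library numbers were used only in alternatives, those of the MI columns only among the MI groups.

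Genes with a group mean of at least 1 FPKM in at least 1 of the 12 groups were tested (10884). log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with 1 mean per group, no covariate and 12 residual degrees of freedom. All 15 contrasts used two-sided moderated tests with Benjamini-Hochberg adjustment over genes, and genes with an adjusted p under 0.05 were called. A pseudocount of 1 understates changes of genes of low expression. Summed FPKM were compared by exact permutation within stages over MI, MII and zygote, a test chosen after the sums were seen. In leave-one-out fits the lone library is assumed to vary like the other groups.

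The contrasts and their tests, the 16 gene lists and their tests, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. Tests of explanations were chosen later. The lists were CCR4-NOT complex and deadenylation, decapping and mRNA decay, cytoplasmic polyadenylation and poly(A) binding, oocyte-specific and maternal-effect genes, meiotic cell cycle regulators, spindle and microtubule genes, ribosomal proteins, nuclear-encoded oxidative phosphorylation, proteasome subunits, translation factors, zygotic genome activation, DNA replication and repair, cumulus and granulosa cell markers, sperm markers, blood and immune markers, and stress and immediate early genes. Lists were tested against other genes with camera (preset inter-gene correlation of 0.01, and an estimated one), with adjustment over the lists of a contrast, and against 0 with fry. Camera asks whether a list moved more or less than other genes, so its direction can differ from the sign of the list's median. Genes named are, per contrast, the 8 highest and 8 lowest log2 changes among called genes with at least 10 FPKM in the higher group, no overlap of the libraries and a gene symbol other than of a predicted locus, the 2 highest and 2 lowest members of each list, and Cnot6l and Btg4; the text gives a subset. Other genes named where a count was 5 or fewer were chosen after their values were seen.

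Sets of genes that fall in WT were called and lower by at least 1 on the log2 scale, and level genes changed by less than 0.25. The WT change that chose a set came from other libraries than those in which the set was measured. The filters on FPKM used all libraries. Calls shared by Cnot6l-/- and the group labelled Btg4-/- were set beside 100 simulated draws of unchanged groups against the same WT libraries. The fit was tested on simulated data built on the Cnot6l-/- and WT MII eggs: of 50 genes changed by each size, it called 0 at a log2 change of 0.5, 5 at 1, 38 at 2 and 47 at 3, and 2 of 10684 unchanged genes. Few genes were changed, all well expressed in WT MII eggs, so these rates do not give the power of contrasts with many more calls. Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling of each library over genes above 1 FPKM in all libraries, only the libraries of the groups compared, the library number as a block, a fall of at least 2, each library left out in turn and the estimated correlation. A fit without the MI libraries and one with the MI column number as a block were added after seeing the data. Motifs were searched in 3′ UTRs of at least 50 bases of the gencode vM1 annotation on mm9, for genes with a mean of at least 5 FPKM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.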

Results

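RNA was sequenced from mouse oocytes and zygotes of 3 genotypes at 4 stages, with 2 libraries in each of 12 groups and 24 libraries in all. The genotypes were wild type (WT), Cnot6l-/- and a group labelled Btg4-/-. Cnot6l encodes a catalytic subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNA, and Btg4 encodes an adaptor of the BTG/Tob family that binds this complex. The stages were oocytes at the germinal vesicle stage (GV), cultured oocytes in the first meiotic division (MI), cultured eggs in the second (MII) and zygotes. The comparisons ask which transcripts fall between the GV oocyte and the zygote, and how far they fall when CNOT6L or BTG4 is missing. Values are FPKM as deposited, and 10884 of the 23235 genes listed were tested. After median-ratio scaling the same filter kept 9823 genes, so the tested members of a list can differ between the 2 settings. This scaling levels the libraries on the 3677 genes above 1 FPKM in all of them. Higher or lower after scaling is therefore relative to those genes, and higher need not mean a rise in the deposited values. Read depth is unknown, since FPKM values do not carry it. Words such as fell, lost, gone and kept refer to FPKM, not to measured amounts of mRNA. The p-values measure only the spread between these libraries, because the labels do not say whether replicates came from separate animals. Ribosomal protein, tubulin and histone genes and the oogenesin gene Oog1 have close copies in the genome, so their single values are uncertain where reads could be split between copies.

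The Cnot6l transcript (chromosome 5, 96505816 to 96591009, minus strand, mm9) was low in every Cnot6l-/- library. It averaged 49.0 ± 35.2 FPKM in WT and 5.11 ± 1.15 in Cnot6l-/- oocytes at GV (SD, n = 2), 18.9 ± 4.41 and 4.65 ± 0.76 at MI, 22.2 ± 1.98 and 5.33 ± 2.73 at MII, and 19.3 ± 17.4 and 5.54 ± 0.87 in zygotes. The log2 change against WT was -2.84 ± 0.65 (SE) at GV (adjusted p = 0.0073), -1.81 ± 0.65 at MI (adjusted p = 0.022) and -1.94 ± 0.65 at MII (adjusted p = 0.021). In zygotes the change of -1.32 ± 0.65 did not pass (adjusted p = 0.27), and after median-ratio scaling it was -2.00 (adjusted p = 0.0092). The Btg4 transcript (chromosome 9, 50924106 to 50927805, plus strand) was at WT level in the libraries labelled Btg4-/-, with 2078 ± 618 FPKM against 2305 ± 261 at GV, 1538 ± 105 against 1047 ± 216 at MI, 1302 ± 271 against 1035 ± 111 at MII and 985 ± 311 against 664 ± 155 in zygotes. None of these 4 differences passed (adjusted p from 0.12 to 0.81), although at MI the log2 difference of 0.57 turned to -0.65 and passed after scaling (adjusted p = 0.017). The allele is not described in the labels, so a normal transcript level does not check this label.

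**Figure D1:**
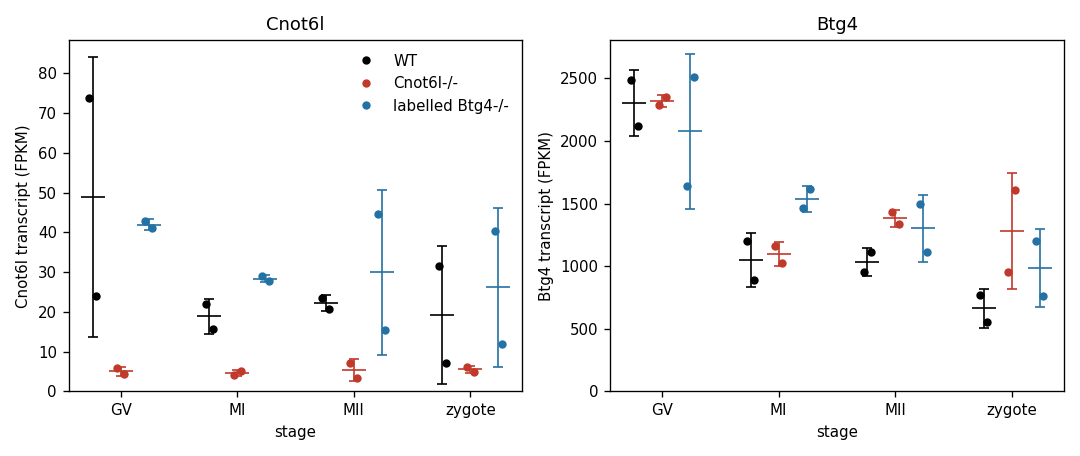
FPKM of the Cnot6l and Btg4 transcripts by stage (x axis). Points are single libraries and bars the mean with its SD (n = 2). The 8 Cnot6l-/- libraries lie between 3.40 and 7.26 FPKM of Cnot6l, and Btg4 lies near the WT level in the libraries labelled Btg4-/-.

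Summed over all genes, FPKM fell from GV to zygote in all genotypes. A larger share of the GV sum remained at each later stage without CNOT6L and in the libraries labelled Btg4-/-. WT libraries went from 497690 ± 64994 at GV to 159243 ± 34476 at MI, 98984 ± 5931 at MII and 62984 ± 18461 in zygotes (SD, n = 2), which is 32.0%, 19.9% and 12.7% of the GV sum. Cnot6l-/- libraries kept 62.5%, 39.4% and 22.6% of their own GV sum at these stages, and those labelled Btg4-/- kept 78.0%, 34.7% and 30.2%. At GV Cnot6l-/- and the group labelled Btg4-/- each had 0.97 times the WT sum. At MI, MII and zygote the ratios to WT were 1.89, 1.92 and 1.73 in Cnot6l-/-. In the group labelled Btg4-/- they were 2.37, 1.7 and 2.32, so the difference was present by MI and did not widen steadily afterwards. Over MI, MII and zygote, Cnot6l-/- sums were 1.86 times those of WT, and 6 of 6 libraries lay above both WT libraries of their stage (exact two-sided permutation test within stages, p = 0.0093, the smallest it can give; adjusted p = 0.014 over 3 comparisons). Sums of the libraries labelled Btg4-/- were 2.1 times those of WT, also in 6 of 6 libraries (exact permutation p = 0.0093, adjusted p = 0.014). These 2 groups differed by 0.88-fold (exact permutation p = 0.37, adjusted p = 0.37).

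**Figure D2:**
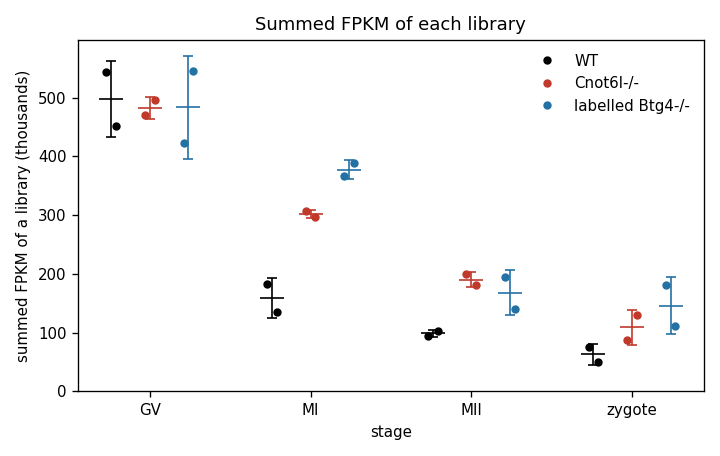
Summed FPKM of each library (y axis) by stage (x axis). Points are libraries and bars the mean with its SD (n = 2); from MI on, the points of both other groups lie above the WT points of their stage.

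In WT oocytes, transcripts for making and degrading proteins were among those that fell most between GV and MI. Fcf1, a factor of ribosomal RNA processing, went from 424 ± 121 to 3.84 ± 0.53 FPKM (SD, n = 2; log2 change -6.43 ± 0.62 SE, adjusted p = 1.5e-07). Psma6, a proteasome subunit, went from 296 ± 60.1 to 4.38 ± 0.48 FPKM (-5.78 ± 0.49, adjusted p = 3.2e-08), and Zar1l, a relative of the maternal-effect gene Zar1, from 414 ± 49.9 to 6.55 ± 0.69 (-5.78 ± 0.33, adjusted p = 8.4e-10). Among the few that rose were the serine protease inhibitor gene Spink2 (3.37 ± 0.66, adjusted p = 0.00026) and the kinesin gene Kif20a, from 10.5 ± 1.63 to 25.7 ± 5.98 FPKM (1.20 ± 0.36, adjusted p = 0.0072). In all, 82 genes rose and 7090 fell, with a median log2 change of -0.95 over all genes. After median-ratio scaling this median was -0.16, and 1494 genes were higher and 2999 lower.

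Ribosomal protein transcripts led this fall from GV to MI, with 78 of 79 lower (78 when adjusted over the list alone) and a median log2 change of -3.97. Nuclear-encoded genes of oxidative phosphorylation fell in 73 of 77 cases (75 adjusted over the list alone, median -2.85), proteasome subunits in 28 of 31 (29 adjusted over the list alone, median -3.29) and translation factors in 33 of 38 (34 adjusted over the list alone, median -2.18). Against other genes the camera test gave adjusted p = 1.92e-18, 8.88e-09, 4.22e-05 and 0.000916, and adjusted p = 0.463, 0.678, 0.678 and 0.678 with an estimated correlation. Examples are Rpl24 (-5.69), Ndufb7 of complex I (-5.37) and the initiation factor subunit Eif3m (-5.36). Lists tied to the oocyte fell less than other genes, so that camera called them up while their medians were negative. Of 42 oocyte-specific and maternal-effect genes 16 fell (14 adjusted over the list alone, median -0.70, camera adjusted p = 0.00725, adjusted p = 0.698 with an estimated correlation). Of 50 meiotic regulators 26 fell (24 adjusted over the list alone, median -0.88, camera adjusted p = 0.0221, adjusted p = 0.698 with an estimated correlation). Of 38 spindle genes 16 fell and Kif20a rose (15 and 1 adjusted over the list alone, median -0.55, camera adjusted p = 0.00258, adjusted p = 0.698 with an estimated correlation). Ooep of the subcortical maternal complex fell by 3.23 and the kinase gene Cdk1 by 3.59, whereas Padi6 (0.75, adjusted p = 0.15), the egg protease gene Astl (0.59, adjusted p = 0.12) and Cdc20, an activator of the anaphase-promoting complex (0.58, adjusted p = 0.11), did not pass. After scaling these 3 were called higher (2.01, 1.85 and 1.82), and the medians of the 3 lists turned positive (0.53, 0.26 and 0.62). The cumulus cell markers Inha, Fshr, Nr5a2 and Gja1 fell too, 4 of 5 (4 adjusted over the list alone, median -1.25, -0.49 after scaling), as did the sperm markers Prm2, Oaz3 and Ldhc, 3 of 5 (3 adjusted over the list alone, median -1.06, -0.90 after scaling), all named after their values were seen.

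By MII the fall in WT covered most genes, and the same kinds of transcripts had nearly gone. Timm17a, of the mitochondrial protein import machinery, went from 675 ± 12.4 FPKM at GV to 2.04 ± 0.21 at MII (SD, n = 2; log2 change -7.80 ± 0.44 SE, adjusted p = 9.1e-11). The proteasome gene Psmb1 went from 358 ± 38.1 to 0.88 ± 0.09 (-7.58 ± 0.33, adjusted p = 1e-11). The initiation factor gene Eif1ax went from 685 ± 22.3 to 2.88 ± 1.11 (-7.50 ± 0.50, adjusted p = 5.8e-10) and the chaperone gene Hspa8 from 701 ± 21.1 to 7.14 ± 0.49 (-6.43 ± 0.27, adjusted p = 1e-11). Of the genes tested 9074 fell and 6 rose, and these 6 were small RNA genes listed at 0 in both GV libraries. The median log2 change was -1.37 over all genes, and -0.37 after scaling, when 1459 genes were higher and 4240 lower. Scaling reversed 630 calls from lower to higher, where higher is relative to the genes used for scaling.

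Nearly all housekeeping transcripts listed were lower at WT MII, among them 79 of 79 ribosomal protein genes (79 adjusted over the list alone, median -5.64) and 76 of 77 oxidative phosphorylation genes (76 adjusted over the list alone, median -4.79). So were 30 of 31 proteasome genes (30 adjusted over the list alone, median -4.33) and 36 of 38 translation factors (36 adjusted over the list alone, median -3.17). Their camera adjusted p-values were 5.34e-20, 4.25e-13, 2.97e-06 and 0.00648, and adjusted p = 0.358, 0.555, 0.628 and 0.899 with an estimated correlation. After scaling they were 8.97e-15, 1.64e-11, 5.45e-05 and 0.0765, and 0.27, 0.266, 0.266 and 0.266. Genes that act on poly(A) tails and mRNA decay moved too. Pabpn1l, a poly(A)-binding protein of the egg, fell from 450 ± 49.2 to 24.5 ± 0.81 FPKM (SD, n = 2; -4.14 ± 0.35). The embryonic poly(A)-binding protein gene Pabpc1l went from 45.4 ± 1 to 1.04 ± 0.29 (-4.51 ± 0.29). The CCR4-NOT subunit gene Rqcd1 went from 28.9 ± 3.81 to 2.28 ± 0.06 (-3.18 ± 0.30). The exosome gene Exosc5 fell by 4.44. Of the CCR4-NOT and deadenylation list 13 of 19 fell (13 adjusted over the list alone), and of the decapping and decay list 20 of 27 (20 adjusted over the list alone). Of the cytoplasmic polyadenylation and poly(A)-binding list 14 of 20 fell (14 adjusted over the list alone), with no call against other genes (camera adjusted p = 0.784, 0.632 and 0.954). After scaling these lists were split, with 6 higher and 8 lower of 19 (median 0.43), 8 and 9 of 25 (median 0.36) and 4 and 8 of 20 (median -0.07). The deadenylase gene Pan2 (-0.37, adjusted p = 0.24), the securin gene Pttg1 (-0.57, adjusted p = 0.18), Mcm2 (-0.29, adjusted p = 0.50) and the maternal gene Zbed3 (-0.07, adjusted p = 0.87) did not pass, and after scaling all 4 were called higher (1.36, 1.37, 1.5 and 1.86). Cumulus and sperm markers were lower in 5 of 5 cases each (5 and 5 adjusted over the list alone, medians -1.42 and -1.53, and -0.44 and -1.39 after scaling). These were Inha, Cyp19a1, Fshr, Nr5a2, Gja1, Prm2, Odf1, Odf2, Oaz3 and Ldhc, named after their values were seen, and Cyp19a1 was higher after scaling (0.58). Of 3 blood markers Laptm5 was lower, also named after its value was seen (1 adjusted over the list alone, median 0), and camera placed this list above other genes (adjusted p = 0.0113, adjusted p = 0.307 with an estimated correlation). Btg4 itself fell by 1.15 and was called higher after scaling (0.78, adjusted p = 0.0037).

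From MII to the zygote, some transcripts that hold or mark the unfertilised egg fell in WT. MII eggs came from culture and zygotes were collected after hCG. Differences between these stages, in any genotype, therefore cannot be assigned to fertilisation alone. Mos, the kinase that maintains the MII arrest, went from 176 ± 50.3 to 8.86 ± 8.17 FPKM (SD, n = 2; log2 change -4.44 ± 0.50 SE, adjusted p = 8.9e-05). Astl, whose protease cleaves the zona pellucida after fertilisation, went from 56.4 ± 3.48 to 3.58 ± 1.46 (-3.69 ± 0.33, adjusted p = 1.2e-05). The zona gene Zp2 went from 90.9 ± 63.6 to 7.70 ± 0.13 (-3.20 ± 0.48, adjusted p = 0.00098) and the plasminogen activator gene Plat from 115 ± 24.1 to 11.5 ± 9.06 (-3.42 ± 0.41, adjusted p = 0.00014). Some transcripts rose, such as Gemin7 of the SMN complex, from 1.92 ± 0.15 to 13.9 ± 5.47 (2.30 ± 0.30, adjusted p = 0.00031). The arginase gene Arg2 also rose, the 1 called member of the 16 tested zygotic genome activation genes (2.49 ± 0.56, adjusted p = 0.015; 1 higher and 1 lower when adjusted over the list alone). In the oocyte-specific list 8 of 42 genes fell and 2 rose, Oog1 (1.91) and Zar1l (1.39; 2 higher and 18 lower when adjusted over the list alone, median -0.83). The camera test placed this list below other genes (adjusted p = 1.54e-06; adjusted p = 0.987 with an estimated correlation), and after scaling 4 rose and 9 fell (median -0.34, adjusted p = 0.00154, adjusted p = 0.376 with an estimated correlation). Cumulus markers also lay below other genes after scaling, with Cyp19a1 and Bex1 lower of the 5 tested then (3 lower over the list alone, median -0.60, camera adjusted p = 0.0412, adjusted p = 0.146 with an estimated correlation). Bex1 was not among the 5 tested as deposited. In the spindle list Kif23, Kif2c, Cenpa and Bub1b fell and Tubb4b rose, of 38 tested (2 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.00265, adjusted p = 0.987 with an estimated correlation). Members of these short counts were chosen after their values were seen. In all 113 genes rose and 350 fell, and after scaling 1476 were higher and 477 lower. The count of 463 depends on single libraries, being 208 without WT MII replicate 1, 101 without WT MII replicate 2 and 160 without WT zygote replicate 1. With only these 4 libraries in the limma fit it was 0, with 1472 genes at an unadjusted p under 0.05.

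At GV, before the fall begins, Cnot6l-/- and the group labelled Btg4-/- differed from WT in few transcripts of the housekeeping lists. In Cnot6l-/- oocytes Pnpla3, a lipid droplet protein gene, was at 0.16 ± 0.07 FPKM against 69.4 ± 4.26 in WT (SD, n = 2; log2 change -5.92 ± 0.28 SE, adjusted p = 1.6e-10). The splicing factor gene Cdc5l was at 0.99 ± 0.50 against 42.2 ± 1.85 (-4.46 ± 0.32, adjusted p = 5.1e-08) and the lysosomal mannosidase gene Manba at 0.19 ± 0.04 against 19.1 ± 1.75 (-4.08 ± 0.28, adjusted p = 2.4e-08). Atpbd4 was higher at 86.9 ± 38.6 against 5.08 ± 1.88 (3.82 ± 0.64, adjusted p = 0.00058), and the meiotic kinase gene Aurkc at 315 ± 32.1 against 102 ± 22.1 (1.63 ± 0.43, adjusted p = 0.021). Iqcf1 and Defb8 had 22.3 ± 3.90 and 18.1 ± 3.75 FPKM in Cnot6l-/- and were listed at 0 in both WT libraries. In all 660 genes were higher and 329 lower, and 539 and 203 after scaling. None of 79 ribosomal protein, 31 proteasome, 38 translation factor and 42 oocyte-specific genes was called by limma (0 each when adjusted over the list alone; 0, 1, 1 and 1 at an unadjusted p under 0.05). Uqcrc1 was the 1 oxidative phosphorylation gene of 77 (1.09, adjusted p = 0.011; 0 over the list alone), and Aurkc the 1 meiotic regulator of 50 (0 over the list alone). Of 5 sperm markers Odf1 and Ldhc were higher, named after their values were seen (3 adjusted over the list alone, median 0.49). With only the 4 libraries compared, 204 genes were called.

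In GV oocytes labelled Btg4-/- the elongation factor-like gene Tceal8 was at 1.47 ± 0.98 FPKM against 146 ± 59.7 in WT (SD, n = 2; log2 change -5.89 ± 0.58 SE, adjusted p = 6.7e-06), and the lens filament gene Bfsp1 at 0.05 ± 0.01 against 21.6 ± 3.02 (-4.43 ± 0.19, adjusted p = 4.9e-10). Bfsp1 was as low in Cnot6l-/- oocytes (-4.47 ± 0.19, adjusted p = 1.1e-10). Lypd3 was higher in both groups, at 33.7 ± 10.2 FPKM in Cnot6l-/- and 23.0 ± 8.13 in the group labelled Btg4-/- against 1.88 ± 1 in WT (3.60 ± 0.43, adjusted p = 1.5e-05, and 3.06 ± 0.43, adjusted p = 0.00027). In this group 664 genes were higher and 145 lower, and 101 and 73 after scaling. None of the ribosomal protein, oxidative phosphorylation, proteasome and oocyte-specific genes was called by limma (0 each when adjusted over the list alone; 2, 3, 0 and 2 at an unadjusted p under 0.05). Of 38 translation factors Eif3b was higher, of 50 meiotic regulators Rps6ka1, of 38 spindle genes Kifc1 and of 16 zygotic genome activation genes Zscan4d, named after their values were seen (0, 1, 1 and 0 adjusted over the list alone). Camera placed ribosomal protein genes below other genes (median -0.02, adjusted p = 0.0352; adjusted p = 0.985 with an estimated correlation). The count of 809 was 488 without WT GV replicate 2, 349 without GV replicate 1 labelled Btg4-/-, 1259 without its replicate 2, and 23 with only the 4 libraries compared.

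At MI, Cnot6l-/- oocytes and those labelled Btg4-/- still held much of what WT had lost. Zar1l stood at 178 ± 2.75 FPKM in Cnot6l-/- and 214 ± 13.5 in the group labelled Btg4-/-, against 6.55 ± 0.69 in WT (SD, n = 2; log2 change 4.57 ± 0.33 SE, adjusted p = 1.2e-08, and 4.83 ± 0.33, adjusted p = 4.9e-09). The complex I gene Ndufb7 stood at 95.2 ± 0.70 and 109 ± 10.6 against 2.91 ± 0.37 (4.62 ± 0.23, adjusted p = 7.8e-10, and 4.82 ± 0.23, adjusted p = 1.1e-09). The beta-tubulin gene Tubb4b stood at 569 ± 32.4 and 662 ± 27.6 against 43.3 ± 5.79 (3.69 ± 0.27, adjusted p = 1.3e-08, and 3.91 ± 0.27, adjusted p = 5.5e-09). Psma6 stood at 94.5 ± 0.97 and 119 ± 12.8 against 4.38 ± 0.48 (4.15 ± 0.49, adjusted p = 1.6e-06, and 4.48 ± 0.49, adjusted p = 5.8e-07). Cnot10, a CCR4-NOT subunit gene, was also higher in both (2.73 ± 0.20, adjusted p = 1.2e-08, and 2.50 ± 0.20, adjusted p = 2.1e-08). Spink2, which rose in WT, stayed at 0.74 ± 0.28 and 0.84 ± 0.54 against 19.4 ± 10 (-3.47 ± 0.66, adjusted p = 0.0002, and -3.41 ± 0.66, adjusted p = 0.00021). Pttg1 was lower in Cnot6l-/-, at 1540 ± 104 against 3090 ± 931 (-0.97 ± 0.39, adjusted p = 0.04), as was Pabpn1l (-1.04 ± 0.35, adjusted p = 0.015). In Cnot6l-/- 6565 genes were higher and 141 lower (median 0.87), and after scaling 3517 and 1082 (median 0.28). In the group labelled Btg4-/- 7473 were higher and 47 lower (median 0.99), and after scaling 3193 and 965 (median 0.22).

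Among the lists tested at MI, those of ribosomal protein, oxidative phosphorylation and proteasome genes lay above other genes by camera at the preset correlation. Ribosomal protein genes were higher in 69 of 79 cases in Cnot6l-/- (71 adjusted over the list alone, median 2.81) and in 77 in the group labelled Btg4-/- (77 adjusted over the list alone, median 3.33). The camera test gave adjusted p = 5.22e-08 and 2.11e-11, and adjusted p = 0.742 and 0.821 with an estimated correlation. Oxidative phosphorylation genes were higher in 59 and 66 of 77 cases (61 and 67 adjusted over the list alone; camera adjusted p = 0.018 and 0.00306, adjusted p = 0.742 and 0.821 with an estimated correlation). Proteasome genes were higher in 24 and 26 of 31 (24 and 26 adjusted over the list alone; camera adjusted p = 0.0161 and 0.00808, adjusted p = 0.742 and 0.821 with an estimated correlation). Translation factors were higher in 25 and 29 of 38 (25 and 29 adjusted over the list alone, medians 1.31 and 1.83) and did not pass the camera test (adjusted p = 0.129 and 0.0515). Medians after scaling were, in the same order of lists, 1.91, 0.96, 1.52 and 0.52 in Cnot6l-/-. In the group labelled Btg4-/- they were 2.13, 0.99, 1.59 and 0.65. Oxidative phosphorylation genes were then higher in 40 and 41 cases and lower in 3 and 2. Translation factors were higher in 17 and 20 and lower in 4 and 2. Oocyte-specific genes were higher in 11 and 15 of 42 cases (8 and 11 adjusted over the list alone, medians 0.49 and 0.69), yet camera placed this list below other genes (adjusted p = 0.00718 and 0.00442; adjusted p = 0.742 and 0.821 with an estimated correlation), and after scaling its medians were -0.45 and -0.50. Spindle genes were higher in 13 and 20 of 38 cases (11 and 20 adjusted over the list alone, medians 0.51 and 0.80) and lay below other genes by camera (adjusted p = 0.0161 and 0.048; adjusted p = 0.742 and 0.821 with an estimated correlation). After scaling 4 and 6 of 37 spindle genes were higher, 12 and 11 lower, and the camera call held with an estimated correlation (adjusted p = 0.0198 and 0.0472). Both comparisons use the same 2 WT MI libraries, so these calls are not independent of each other. Sperm markers were higher in 4 and 5 of 5 cases (4 and 5 adjusted over the list alone, medians 1.12 and 1.24, and 0.68 and 0.65 after scaling): Prm2, Odf2, Oaz3 and Ldhc in both groups, and Odf1 in that labelled Btg4-/-. Of 5 cumulus markers 2 and 3 were higher (1 and 3 adjusted over the list alone, medians 0.53 and 0.96, and 0.03 and 0.17 after scaling), Cyp19a1 and Nr5a2 in Cnot6l-/- and Inha, Fshr and Nr5a2 in the other, where the blood marker Laptm5 was higher too, 1 of 3 (1 adjusted over the list alone). These markers were named after their values were seen.

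At MII, Cnot6l-/- eggs kept more than WT of many transcripts, among them those for respiration, ribosomes and protein turnover in the lists below. Some of these transcripts were near 0 in WT. Hint1, a nucleotide hydrolase gene, stood at 267 ± 14.9 FPKM against 4.18 ± 1.85 in WT (SD, n = 2; log2 change 5.74 ± 0.37 SE, adjusted p = 1.7e-08). The calmodulin gene Calm2 stood at 282 ± 81.7 against 5.28 ± 2.93 (5.55 ± 0.70, adjusted p = 7.8e-06) and Ndufb4 of complex I at 139 ± 4.02 against 3.28 ± 0.57 (5.04 ± 0.35, adjusted p = 2.8e-08). Figla, a transcription factor of oocyte genes, stood at 18.5 ± 1.17 against 0.40 ± 0.11 (3.8 ± 0.29, adjusted p = 5.9e-08), and Birc5, of the chromosomal passenger complex, at 344 ± 46.8 against 60.7 ± 15.9 (2.50 ± 0.37, adjusted p = 3.4e-05). Lower in Cnot6l-/- were Pnpla3, at 0.06 ± 0.01 against 17.5 ± 5.50 (-4.09 ± 0.28, adjusted p = 2.4e-08), and Cdc5l, at 0.21 ± 0.14 against 13.3 ± 4.97 (-3.52 ± 0.32, adjusted p = 3.1e-07), both already low at GV. In all 4818 genes were higher and 73 lower (median 0.56), and 3373 and 854 after scaling (median 0.29).

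Of the lists in Cnot6l-/- MII eggs, ribosomal protein genes were higher in 74 of 79 cases (75 adjusted over the list alone, median 2.98), oxidative phosphorylation genes in 71 of 77 (71 adjusted over the list alone, median 2.87). Proteasome genes were higher in 27 of 31 (27 adjusted over the list alone, median 2.13) and translation factors in 22 of 38 (24 adjusted over the list alone, median 1.08). Camera gave adjusted p = 3.86e-23, 2.39e-19, 1.01e-06 and 0.0432, and adjusted p = 0.418, 0.418, 0.568 and 0.869 with an estimated correlation. After scaling 61, 61, 24 and 17 were higher, and 0, 1, 1 and 2 lower (medians 2.43, 2.16, 1.41 and 0.59). Translation factors then no longer stood apart from other genes (adjusted p = 1.7e-12, 6.28e-13, 0.000267 and 0.288, and 0.342, 0.339, 0.342 and 0.342 with an estimated correlation). Examples are Rps13 (4.85), Psmb7 (4.50) and Eif1ax (4.38). Oocyte-specific genes were higher in 19 of 42 cases (19 adjusted over the list alone), such as Zar1l (4.28) and Figla, meiotic regulators in 24 of 50 (24 adjusted over the list alone), such as the MAP kinase gene Mapk3 (2.87), and spindle genes in 13 of 38 (13 adjusted over the list alone), such as Tubb4b (3.31). CCR4-NOT genes were higher in 7 of 19 cases (7 adjusted over the list alone), among them Rqcd1 (1.96), with Cnot6l the 1 lower. Cytoplasmic polyadenylation and poly(A)-binding genes were higher in 9 of 20 cases (9 adjusted over the list alone), such as Pabpc1l (2.90). Decapping and decay genes were higher in 11 of 27 (11 adjusted over the list alone), such as Lsm4 (2.79), and DNA replication and repair genes in 14 of 35 (14 adjusted over the list alone). None of these 7 lists stood apart from other genes (camera adjusted p from 0.39 to 0.984), and after scaling the medians of the spindle, CCR4-NOT and decapping lists turned to -0.24, -0.37 and -0.35. After scaling oocyte-specific genes were higher in 16 cases and lower in 8, meiotic regulators in 17 and 6, spindle genes in 7 and 8, and DNA replication and repair genes in 9 and 5. CCR4-NOT genes were then higher in 4 and lower in 4, poly(A)-binding genes in 6 and 4, and decapping genes in 9 and 5. Sperm markers were higher in 4 of 5 cases and cumulus markers in 2 of 5 (medians 0.81 and 0.07). The decapping cofactor gene Dcp1a (-0.40, adjusted p = 0.42) and Pttg1 (-0.36, adjusted p = 0.49) did not differ as deposited and were called lower after scaling (-1.21 and -1.19).

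MII eggs labelled Btg4-/- also kept respiratory and housekeeping transcripts. Sdhd of complex II stood at 95 ± 17.8 FPKM against 0.63 ± 0.06 in WT (SD, n = 2; log2 change 5.87 ± 0.33 SE, adjusted p = 1.2e-08). Cox17, a copper chaperone for cytochrome oxidase, stood at 301 ± 22.1 against 4.24 ± 0.53 (5.85 ± 0.34, adjusted p = 1.3e-08). Psmb7 stood at 83.8 ± 20.4 against 1.20 ± 1.16 (5.36 ± 0.41, adjusted p = 1.8e-07) and Figla at 21.5 ± 2.79 against 0.40 ± 0.11 (4 ± 0.29, adjusted p = 1.2e-07). Tceal8 was lower, at 1.04 ± 0.50 against 21.9 ± 5.59 (-3.49 ± 0.58, adjusted p = 0.00023), as was the peroxisomal carrier gene Slc25a17, at 3.64 ± 1.89 against 18.0 ± 1.14 (-2.1 ± 0.36, adjusted p = 0.00028). Ribosomal protein genes were higher in 59 of 79 cases (65 adjusted over the list alone, median 1.43), oxidative phosphorylation genes in 62 of 77 (66 adjusted over the list alone, median 1.89). Proteasome genes were higher in 21 of 31 (25 adjusted over the list alone, median 1.61) and translation factors in 16 of 38 (17 adjusted over the list alone, median 0.74). Camera gave adjusted p = 3.45e-14, 2.05e-17, 1.44e-06 and 0.0931, and adjusted p = 0.584, 0.584, 0.584 and 0.957 with an estimated correlation. After scaling the medians were 0.93, 1.27, 1.03 and 0.20 (adjusted p = 3.12e-06, 5e-11, 0.000535 and 0.538, and 0.641, 0.232, 0.318 and 0.641 with an estimated correlation). Of the CCR4-NOT list 5 of 19 were higher (5 adjusted over the list alone), named after their values were seen: Rqcd1 (1.84), the antiproliferative adaptor genes Tob1 (2.48), Tob2 (1.86) and Btg2 (2.06), and the deadenylase gene Parn (1.35). After scaling 5 of this list were higher and 4 lower (median -0.24). Of 5 sperm markers Ldhc was higher and of 3 blood markers Lyz2, also named after their values were seen (1 and 1 adjusted over the list alone). In all 3075 genes were higher and 37 lower (median 0.38), and 2146 and 643 after scaling (median 0.14). The count of 3112 was 2060 without WT MII replicate 2 and 1720 without MII replicate 1 labelled Btg4-/-.

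**Figure D3:**
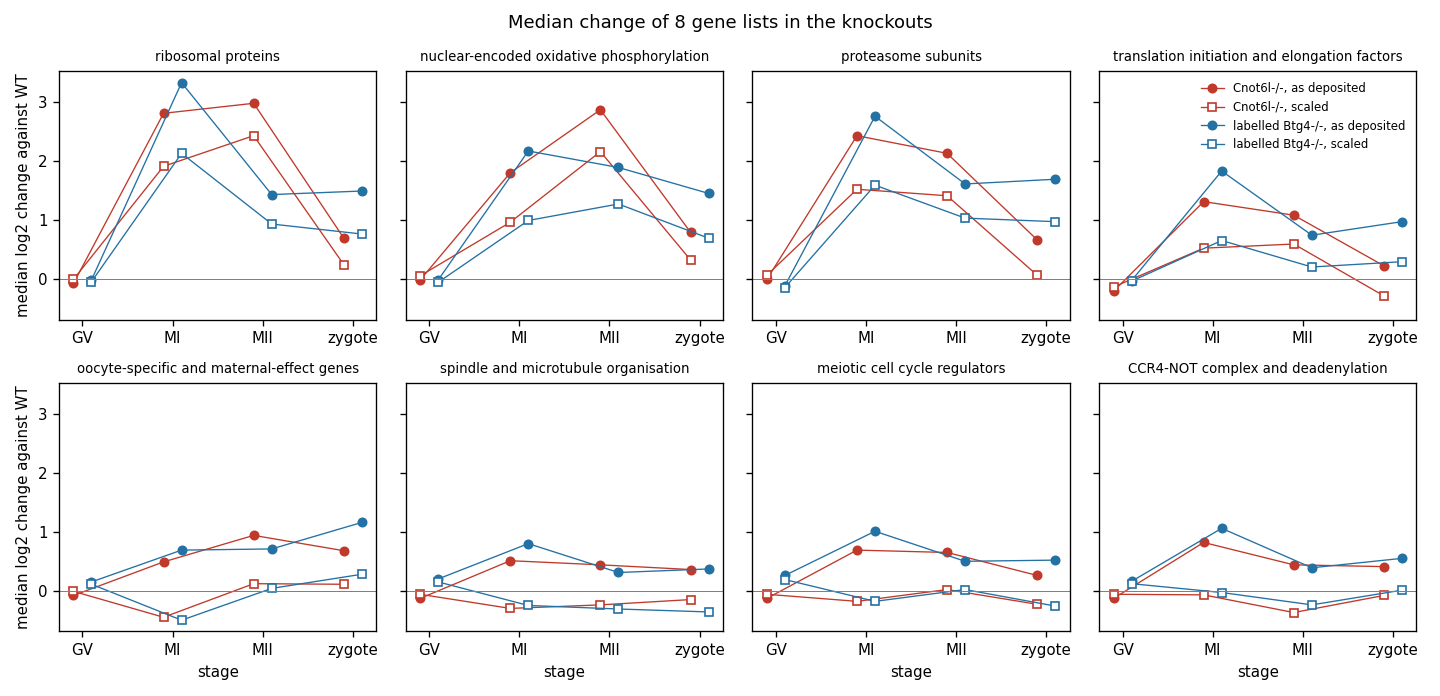
Median log2 change against WT (y axis) of 8 gene lists by stage (x axis) in Cnot6l-/- and in the group labelled Btg4-/-. Filled points are values as deposited and open points values after median-ratio scaling; the ribosomal protein medians lie near 0 at GV and at 2.81 and 3.33 at MI as deposited, and the medians of the spindle list turn negative after scaling from MI on.

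In zygotes Cnot6l-/- and the group labelled Btg4-/- differed. In Cnot6l-/- zygotes transcripts such as Ube2t, an ubiquitin-conjugating enzyme gene, stood at 385 ± 111 FPKM against 18.0 ± 18.9 in WT (SD, n = 2; log2 change 4.80 ± 0.56 SE, adjusted p = 4e-05). Lsm5 stood at 224 ± 69.1 against 10.5 ± 9.98 (4.60 ± 0.59, adjusted p = 0.00012), and Pabpn1l at 86.4 ± 40.5 against 10.1 ± 5.59 (3 ± 0.35, adjusted p = 4e-05). Mos stood at 66.8 ± 34.5 against 8.86 ± 8.17 (2.98 ± 0.50, adjusted p = 0.0012) and the oocyte growth factor gene Gdf9 at 448 ± 166 against 108 ± 51.7 (2.08 ± 0.32, adjusted p = 0.00059). Oog1 was lower, at 3.04 ± 0.38 against 15.3 ± 5.43 (-1.98 ± 0.37, adjusted p = 0.0026). Hspa8 stood at 9.06 ± 1.8 against 16.5 ± 2.91 (-0.80, adjusted p = 0.086) and was called lower after scaling (-1.47, adjusted p = 0.0016). Ribosomal protein genes were higher in 22 of 79 cases (37 adjusted over the list alone, median 0.69), oxidative phosphorylation genes in 24 of 77 (30 adjusted over the list alone, median 0.79). Proteasome genes were higher in 10 of 31 (14 adjusted over the list alone, median 0.66) and oocyte-specific genes in 9 of 42, with Oog1 lower (12 higher and 1 lower adjusted over the list alone, median 0.68). Of 38 translation factors Eif3k was higher (1 adjusted over the list alone, median 0.22, -0.29 after scaling, when Eif1ax, Eef1a1, Eef1d and Eef2 were lower), with camera adjusted p = 0.676. Of 5 cumulus markers Cyp19a1 was higher (1 adjusted over the list alone). These members were named after their values were seen. For the ribosomal protein, oxidative phosphorylation, proteasome and oocyte-specific lists camera gave adjusted p = 2.99e-05, 6.98e-05, 0.00624 and 0.0242, and adjusted p = 0.992 for each with an estimated correlation. After scaling ribosomal protein genes were higher in 9 cases and lower in 3 (median 0.24), oxidative phosphorylation genes in 20 and 8 (median 0.32). Proteasome genes were higher in 5 and lower in 3 (median 0.06) and oocyte-specific genes in 6 and 3 (median 0.11), with camera adjusted p = 0.0915, 0.0452, 0.174 and 0.59, and 0.77, 0.743, 0.743 and 0.779 with an estimated correlation. In all 871 genes were higher and 45 lower (median 0.18), against 786 and 777 after scaling (median -0.08). The count of 916 was 476 without WT zygote replicate 2 and 289 without Cnot6l-/- zygote replicate 2. With only the 4 libraries compared it was 5, named here after their values were seen: Hist1h2bc, Il17f, Pnpla3, E330012B07Rik and Snora33.

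Zygotes labelled Btg4-/- still held respiratory and proteasome transcripts. Cox7c of cytochrome oxidase stood at 195 ± 11.8 FPKM against 1.74 ± 0.98 in WT (SD, n = 2; log2 change 6.21 ± 0.50 SE, adjusted p = 4.9e-07), and Cox17 at 233 ± 30.1 against 3.31 ± 1.11 (5.78 ± 0.34, adjusted p = 3.2e-08). Psmb1 stood at 122 ± 63.0 against 3.37 ± 1.06 (4.74 ± 0.33, adjusted p = 9.6e-08), and Eif3m at 74.3 ± 33.0 against 2.62 ± 1.58 (4.38 ± 0.38, adjusted p = 1.2e-06). Zp2 stood at 118 ± 57.8 against 7.70 ± 0.13 (3.69 ± 0.48, adjusted p = 3.7e-05) and Hspa8 at 103 ± 21.0 against 16.5 ± 2.91 (2.56 ± 0.27, adjusted p = 7.7e-06). Ribosomal protein genes were higher in 50 of 79 cases (56 adjusted over the list alone, median 1.49), oxidative phosphorylation genes in 53 of 77 (56 adjusted over the list alone, median 1.45). Proteasome genes were higher in 26 of 31 (27 adjusted over the list alone, median 1.69), translation factors in 17 of 38 (23 adjusted over the list alone, median 0.97) and oocyte-specific genes in 19 of 42 (20 adjusted over the list alone, median 1.16). Camera gave adjusted p = 1.65e-13, 1.62e-13, 1.62e-13, 0.000832 and 0.000832, and adjusted p = 0.528, 0.528, 0.528, 0.794 and 0.794 with an estimated correlation. After scaling the counts dropped to 26, 30, 17, 9 and 9 higher, with 1, 3, 0, 0 and 1 lower. The scaled medians were 0.76, 0.69, 0.97, 0.29 and 0.28, and camera no longer placed translation factors and oocyte-specific genes above others (adjusted p = 0.0882 and 0.347). In all 2342 genes were higher and 5 lower (median 0.38), and 1154 and 299 after scaling (median 0.01). Of 5 cumulus markers Fshr was higher (1 adjusted over the list alone). This gene and the 5 lower ones were named after their values were seen. The latter were Hist2h2ac (0.16 against 0.63 FPKM), Mtus2 (1.69 against 6.24) and the small RNA genes Mir320, Mir599 and Snora15, listed at 0 in both libraries labelled Btg4-/-. The count of 2347 was 1206 without WT zygote replicate 2 and 1109 without zygote replicate 1 labelled Btg4-/-. With only the 4 libraries compared the limma fit called 0 genes, with 2527 at an unadjusted p under 0.05.

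Genes that fall in WT were then taken as a set. For MII eggs the set was defined from WT zygotes against GV, so that the fall was not measured in the eggs compared. It held 8060 genes, against 290 that stayed level. In Cnot6l-/- eggs 4269 genes of the falling set were higher and 51 lower, with a median log2 change of 0.76 against 0.17 in level genes (camera p = 6.4e-13, p = 0.14 with an estimated correlation). In eggs labelled Btg4-/- 2899 were higher and 29 lower, with a median of 0.53 against 0.08 (camera p = 2.3e-11, p = 0.17 with an estimated correlation). After scaling the falling set held 2420 genes, with medians of 1.32 against 0.10 in Cnot6l-/- (p = 0.0013 with an estimated correlation) and 0.76 against 0.04 in eggs labelled Btg4-/- (p = 0.0077). For zygotes the set was defined from WT MII against GV and held 6936 genes. Its median in Cnot6l-/- zygotes was 0.18 against 0.11 (camera p = 0.86), and -0.20 against 0 after scaling (camera p = 0.028, p = 0.47 with an estimated correlation). As deposited, this median was 0.08 without WT zygote replicate 2 and 0.3 without WT zygote replicate 1. In zygotes labelled Btg4-/- it was 0.60 against 0.06 (camera p = 8.2e-23, p = 0.049 with an estimated correlation), and 0.46 against -0.06 after scaling (p = 0.0039 with an estimated correlation). Level genes as deposited had a median of 0.68 FPKM over all libraries against 6.6 in the falling set for MII, and 0.772 against 6.43 for zygotes.

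The differences of Cnot6l-/- and of the group labelled Btg4-/- from WT overlapped at MII. Calm2, Zar1l, Figla, Psmb7, Mapk3 and Lsm4 were higher in both, and 2603 genes in all were higher in both, 23 lower in both and 11 opposite, where independent lists would share 1361.2 and 0.2. Both comparisons use the same 2 WT libraries, which alone adds to an overlap. Unchanged groups simulated against those libraries shared a median of 0 calls and at most 2 in 100 draws. Groups without a difference have few calls to share, and their genes were drawn independently. The simulated count therefore cannot show what shared WT libraries add to lists as long as these. The covariance of the log2 changes was 0.557 against 0.0531 in the simulation, a difference of 0.504 (0.605 after scaling). The controls were not split, which would leave 1 WT library for each comparison, so part of the excess in shared calls may come from the shared controls. After scaling 1720 genes were higher in both and 389 lower in both. The count of 2626 in the same direction was 1732 without WT MII replicate 2 and 1586 without MII replicate 1 labelled Btg4-/-.

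Compared with each other at MII, Cnot6l-/- eggs had more of several housekeeping transcripts than eggs labelled Btg4-/-. Slc25a17 stood at 66.5 ± 6.26 against 3.64 ± 1.89 FPKM (SD, n = 2; log2 change 3.92 ± 0.36 SE, adjusted p = 2.1e-06). Ndufb7 stood at 28.8 ± 0.42 against 2.46 ± 0.10 (3.11 ± 0.23, adjusted p = 1.8e-07), and Psmb5 at 44.0 ± 0.43 against 4.81 ± 1.12 (2.96 ± 0.25, adjusted p = 9e-07). The polyadenylation factor gene Cpeb1 stood at 41.3 ± 9.02 against 14.2 ± 4.99 (1.5 ± 0.32, adjusted p = 0.0047). Sdhd was lower, at 22.9 ± 5.18 against 95 ± 17.8 (-2.01 ± 0.33, adjusted p = 0.00065). Ribosomal protein genes were higher in 37 of 79 cases and Rpsa and Rps3 lower (40 and 3 adjusted over the list alone, median 1.03), and oxidative phosphorylation genes higher in 22 of 77 with Sdhd and Uqcrfs1 lower (29 and 2 adjusted over the list alone, median 0.66). Camera gave adjusted p = 8.45e-10 and 0.000768, and adjusted p = 0.891 for both with an estimated correlation. In all 1199 genes were higher and 193 lower (median 0.13), and 1365 and 419 after scaling. The count of 1392 was 689 without Cnot6l-/- MII replicate 1, 725 without MII replicate 2 labelled Btg4-/- and 1, the small RNA gene Snora33, with only the 4 libraries compared.

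In zygotes the order turned, and most differences lay in transcripts higher in the group labelled Btg4-/-. Psmb7 stood at 2.78 ± 0.36 FPKM in Cnot6l-/- against 92.7 ± 31.3 (SD, n = 2; log2 change -4.60 ± 0.41 SE, adjusted p = 1.3e-06), and Sdhd at 2.2 ± 0.57 against 78.5 ± 16.3 (-4.63 ± 0.33, adjusted p = 2.1e-07). Eif3m stood at 3.01 ± 0.62 against 74.3 ± 33.0 (-4.17 ± 0.38, adjusted p = 1.8e-06) and Zar1l at 4.54 ± 2.38 against 91.1 ± 18.4 (-4.11 ± 0.33, adjusted p = 5.2e-07). Higher in Cnot6l-/- were the transcription regulator gene Arid5b, at 26.5 ± 6.82 against 0.11 ± 0.03 (4.61 ± 0.57, adjusted p = 4.7e-05), and the radixin gene Rdx, at 315 ± 53.3 against 48.5 ± 23.4 (2.75 ± 0.35, adjusted p = 6.4e-05). Proteasome genes were lower in Cnot6l-/- in 12 of 31 cases (16 adjusted over the list alone, median -0.79), and translation factors in 10 of 38 (12 adjusted over the list alone, median -0.51). Ribosomal protein genes were lower in 33 of 79 cases (39 lower and 7 higher adjusted over the list alone, median -0.83). Oxidative phosphorylation genes were lower in 25 of 77 cases, with Ndufa11, Ndufa12 and Uqcr11 higher, named after their values were seen (26 lower and 3 higher adjusted over the list alone, median -0.58). By camera, adjusted p was 5.71e-05, 0.00078, 0.00134 and 0.00134, and adjusted p = 0.951 for each with an estimated correlation. After scaling it was 0.00176, 0.0143, 0.0682 and 0.0292, and 0.405, 0.142, 0.858 and 0.838 with an estimated correlation, with medians of -0.61, -0.33, -0.66 and -0.44. In all 186 genes were higher and 1393 lower (median -0.15), and 718 and 1668 after scaling. The count of 1579 was 720 without Cnot6l-/- zygote replicate 1 and 780 without zygote replicate 1 labelled Btg4-/-.

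The change from GV to MII was also compared between genotypes as an interaction. In Cnot6l-/- the difference from WT grew from GV to MII for Hint1 (log2 interaction 5.35 ± 0.52 SE, adjusted p = 4.7e-06), Paip2, an inhibitor of the poly(A)-binding protein (5.28 ± 0.84, adjusted p = 0.00023), Rps13 (4.85 ± 0.46, adjusted p = 4.3e-06), Zar1l (4.04 ± 0.47, adjusted p = 2.1e-05) and Pabpn1l (3.42 ± 0.49, adjusted p = 0.0001). In the group labelled Btg4-/- it grew for Paip2 (6.18 ± 0.84, adjusted p = 0.00014), Sdhd (5.89 ± 0.47, adjusted p = 1e-06), Psmb7 (5.53 ± 0.57, adjusted p = 1.5e-05) and Pabpn1l (3.02 ± 0.49, adjusted p = 0.00061). In Cnot6l-/- the interaction was positive for 70 of 79 ribosomal protein genes (73 adjusted over the list alone, median 3; camera adjusted p = 2.02e-29, adjusted p = 0.293 with an estimated correlation). In the group labelled Btg4-/- it was positive for 41 (52 adjusted over the list alone, median 1.64; camera adjusted p = 1.86e-15, adjusted p = 0.606 with an estimated correlation). Counts were 2619 positive and 78 negative in Cnot6l-/- (1473 and 72 after scaling), and 1451 and 63 in the group labelled Btg4-/- (1217 and 234 after scaling). The latter total of 1514 was 947 without WT GV replicate 1, 898 without WT MII replicate 2, 939 without GV replicate 1 and 760 without MII replicate 1 labelled Btg4-/-.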

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

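The tests of a single scale factor described here were chosen after the result was seen. The difference from WT changed between GV and MII by a test of the interaction, in 2697 genes for Cnot6l-/- and 1514 for the group labelled Btg4-/-. Both groups also differed from each other in a direct test, in 1392 genes at MII and 1579 in zygotes. Genes that differ in these tests include Hint1 and Paip2 in the Cnot6l-/- interaction, and Sdhd and Psmb7 between the zygotes.

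Genes that fall in WT were higher at MII in Cnot6l-/- eggs and in eggs labelled Btg4-/-, which is the direction expected if CNOT6L and BTG4 promote mRNA loss. A single scale factor per library would move falling and level genes alike, but after median-ratio scaling their medians still differed. Among genes with a mean of at least 5 FPKM, 1564 falling and 695 level, the difference was 1.75 in Cnot6l-/- (1.67 to 1.81 with each MII library left out) and 1.16 in eggs labelled Btg4-/- (1.08 to 1.22). This mean was taken over all libraries, also those measured, so falling genes that were high in these 2 groups passed more easily. Among all 2420 falling and 2239 level genes the difference was 1.22 and 0.73. After a trend on transcript length and GC content was removed among the genes of at least 5 FPKM, the differences were 1.41 (1.33 to 1.45) and 1.04 (0.91 to 1.07), which argues against such a bias as the whole cause. Slower loss of maternal mRNA may therefore be a candidate explanation, but FPKM do not separate the amount of an mRNA from how well it entered the library. A slower meiotic progression of these oocytes stays open, since the labels give the hours of culture but not the stage reached by each cell.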

How the results depend on the processing

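The fit without the MI libraries and the block at MI were chosen after seeing the data, and the other alternatives were planned. Scaling to spike-in RNA was not run, as the table holds no spike-in transcripts, and the planned block was fitted on 18 libraries, without MI. The cause of the changes below was not tested, except where fewer libraries or genes enter the fit.

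With a pseudocount of 0.1 the counts of called genes were 1226 for WT zygotes against MII, 569 and 183 for Cnot6l-/- and the group labelled Btg4-/- against WT at GV, and 1621 for Cnot6l-/- zygotes. The medians of WT-falling genes in these 2 groups were then 1.23 and 0.88 at MII and 0.38 and 0.87 in zygotes, each on the same side of the test. Without a filter the counts were 1714 and 1501 at GV, and the median of WT-falling genes in Cnot6l-/- zygotes, 0.18, passed. With a fall of at least 2 the medians of WT-falling genes rose to 1.32 and 0.93 at MII and 0.92 in zygotes labelled Btg4-/-, and each of the 4 results kept its side of the test.

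After median-ratio scaling the counts were 4493 for WT MI against GV, 5699 for WT MII against GV, 1953 for WT zygotes against MII, 1563 for Cnot6l-/- zygotes, 174, 4158 and 1453 for the group labelled Btg4-/- at GV, MI and zygote, 2386 between zygotes of the 2 groups and 1545 for the Cnot6l-/- interaction. WT-falling genes in Cnot6l-/- zygotes reversed to -0.20. Reversed genes were Btg4 in WT at MI (0.11) and MII (0.78), Mcm2 (1.5), Zbed3 (1.86), Pttg1 (1.37), Pan2 (1.36), Cyp19a1 (0.58) and Odf2 (0.27) in WT at MII, Cyp19a1 (-0.14) at MI in Cnot6l-/-, and Btg4 at MI in Cnot6l-/- (-0.87) and in the group labelled Btg4-/- (-0.65). Genes count as reversed where the sign changed and the gene was called in either setting. Odf2 in WT at MII and Cyp19a1 at MI in Cnot6l-/-, for example, were not called after scaling. No other alternative reversed a named gene.

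With only the libraries compared, which leaves 2 residual degrees of freedom per contrast of 2 groups, limma called 0 genes for WT zygotes against MII (1472 at an unadjusted p under 0.05), 204 for Cnot6l-/- and 23 for the group labelled Btg4-/- at GV, 5 for Cnot6l-/- zygotes (1610 unadjusted), 0 for zygotes labelled Btg4-/- (2527 unadjusted), 1 between the 2 groups at MII (2164 unadjusted) and 736 for the interaction of the group labelled Btg4-/-. Without the MI libraries the counts were 204 for WT zygotes against MII, 557 for Cnot6l-/- zygotes, 500 for the group labelled Btg4-/- at GV and 1051 between zygotes of the 2 groups. With an estimated correlation 0 of the 56 list calls passed, and after scaling 4 of 55. Over all 240 list tests as deposited, 6 had an unadjusted camera p under 0.05 with an estimated correlation. Over the same 240 tests fry, which tests another question, called 134.

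With each library left out, counts ranged from 349 to 1259 for the group labelled Btg4-/- at GV, 760 to 1779 for its interaction, 1720 to 3163 at MII and 1109 to 2693 in zygotes. They ranged from 101 to 495 for WT zygotes against MII, 289 to 1185 for Cnot6l-/- zygotes, 1586 to 2606 for calls shared at MII, 689 to 1087 between the 2 groups at MII and 720 to 1531 in zygotes. Libraries that moved a count by over 1.5 times are named with each comparison. Of 90 such values 68 stayed within 1.5 times the count or on the same side of the test.

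The library numbers could mark pairs in part of the data. Over 36 pairs of equal number, correlations of the residuals ran from -0.31 to 0.71 (median 0.44), with 28 over 0.1 and 4 under -0.1. Of 18 libraries 16 correlated best with one of their own number. The residuals of the 2 libraries of a group mirror each other, so both always give the same answer and are not separate counts. The 8 pairs that include GV labelled Btg4-/- ran from -0.31 to 0 and the other 28 from 0.28 to 0.71, so the numbers do not pair that group, and its blocked count at GV rests on a pairing the residuals do not show. With the number as a block the counts were 9484 for WT MII against GV, 495 for WT zygotes, 1090, 5257 and 1019 for Cnot6l-/- at GV, MII and zygote, 866, 3370 and 2572 for the group labelled Btg4-/-, 1441 and 1673 between the 2 groups, 2984 and 1808 for the interactions and 2852 shared. With the MI column number as a block they were 6595 and 7363 at MI. No paired analysis was possible for WT MI against GV because these columns share only 1 number.

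Of 2427 values for named genes under these alternatives 2122 kept direction and call, 267 lost the call, 27 gained one and 11 reversed. Depth is unknown, so its limit on genes of low expression cannot be given.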

Other observations

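The tests of mislabelling, of WT libraries that stand apart and of a segment around Cnot6l described here were chosen after the result was seen. Lists of other cell types and programmes were not called against other genes at MII in Cnot6l-/- eggs by camera. The sperm markers Prm2, Odf1, Oaz3 and Ldhc were higher, 4 of 5 tested (4 adjusted over the list alone, median 0.81, camera adjusted p = 0.328), as were the cumulus markers Cyp19a1 and Nr5a2, 2 of 5 (2 adjusted over the list alone, median 0.07, camera adjusted p = 0.39). Of the stress and immediate early genes Egr1, Ddit3, Hspa8, Hsph1 and Dnajb1 were higher, 5 of 11 (5 adjusted over the list alone, median 0.52, camera adjusted p = 0.888), and of the zygotic genome activation genes Zscan4d, Eif1a, Zfp42, Arg2 and Sp110, 5 of 16 (5 adjusted over the list alone, median 0.51, camera adjusted p = 0.752). The 3 blood and immune markers had a median of 0, with 0 called by limma and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.279). After scaling the sperm, cumulus, stress and genome activation medians were 1.06, 0.04, 0.44 and -0.08, with 3 of 4 sperm markers higher, 5 of 11 stress genes higher and 1 lower, and 2 of 14 genome activation genes higher and 1 lower. Of the 5 cumulus markers limma then called 0 higher and 1 lower, with 1 at an unadjusted p under 0.05. Members named here were chosen after their values were seen.

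In WT the spindle list lay above other genes from GV to MI after median-ratio scaling, with 14 of 37 genes higher and 6 lower (median 0.62, against -0.55 as deposited; camera adjusted p = 0.0414 with an estimated correlation). The spindle calls of both other groups against WT at MI use the same WT MI libraries, so they are not independent of this call. Translation factors lay below other genes, with 1 of 38 higher and 24 lower after scaling (median -1.05; adjusted p = 0.0446 with an estimated correlation).

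The Btg4 transcript stood at WT level in the libraries labelled Btg4-/-. WT oocytes under a wrong label would differ from WT no more at MII than at GV, but after scaling 2789 genes were called at MII and 174 at GV, a ratio of 16 (11.1 to 25.9 with each library left out). As deposited the ratio was 3.8 (2.3 to 9.1), which stays above the 1.5 allowed for a wrong label, though not above 3 in every setting. Cnot6l-/- oocytes under a wrong label would lack the Cnot6l transcript, but the lowest library labelled Btg4-/- had 12.05 FPKM and the highest labelled Cnot6l-/- 7.26. An allele that keeps the transcript and ends the protein may explain the level, and was not tested.

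Both as deposited and after scaling 117 genes differed from WT at all 4 stages in Cnot6l-/-, with 104 higher and 13 lower, among them Pnpla3, Cdc5l, Manba and Stk32a; in the group labelled Btg4-/- there were 13, all higher. WT libraries that stand apart would move these genes alike in both groups, but their median change was 1.58 in Cnot6l-/- and 0.12 in the group labelled Btg4-/- (bootstrap interval over genes 0.06 to 0.19; 0.09 to 0.14 with each library left out), which argues against it. The bootstrap interval comes from draws of genes, so it measures neither the spread between libraries nor the correlation of genes. A segment of another strain around Cnot6l would place such genes on its chromosome, but 2.6% lay there against 6.7% of tested genes, the nearest 40.9 Mb away, which argues against it. Segments elsewhere would place such genes close together, and 29.1% had another within 2 Mb against a median of 25.6% in random sets (permutation p = 0.31). This pooled share can miss a single group of genes. Cdkn1b, Ddx47, Ptpro, Arntl2, E330012B07Rik and Pthlh, for example, lie on chromosome 6 between 134870419 and 147212607, named after their positions were seen. A lasting effect of the knockout and strain segments elsewhere cannot be told apart, because the share lies between the bounds set for either.

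Known 3′ UTR motifs were tested as a hypothesis on which transcripts stay high at MII, over 4037 genes with values after median-ratio scaling, in a model with expression, lengths and GC content. Genes with an AU-rich element were predicted to be higher and had a coefficient of -0.143 in Cnot6l-/- (95% interval -0.224 to -0.058, adjusted permutation p = 0.0023) and -0.13 in eggs labelled Btg4-/- (-0.202 to -0.054, adjusted permutation p = 0.0023). Genes with a cytoplasmic polyadenylation element had -0.453 (-0.544 to -0.37) and -0.364 (-0.449 to -0.275), each with adjusted permutation p = 0.0002. In Cnot6l-/- the median change after scaling was -0.01 with this element and 0.96 without. Over these genes the values argue against either motif as a mark of the transcripts that stay high, and point the other way. The intervals and p-values come from draws of genes, so they measure neither the spread between libraries nor the correlation of genes. The fall in WT was not in the model, so the coefficients do not show what either motif does.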
